A study of Mus musculus with 4 samples.

How the data were processed

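Gene expression was measured in 4 cultures of mouse aortic smooth muscle cells, 2 control and 2 given PGE2, with 1 Agilent array each. Per the labels' protocols, cells came from aortic explants, total RNA was amplified and labelled with Cy3 using Agilent's Low Input Quick Amp kit, and the groups were assigned here from the sample titles. The labels call the cultures biological replicates and do not say that equal numbers mark cultures handled together, so the fit had no block for the replicate number.

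The deposited scanner files hold an intensity per spot. Per the file headers, Agilent Feature Extraction 11.5.1.1 with protocol GE1_1105_Oct12 made them for array design 074809, with probe positions on build mm9, while the submitters' processing notes name version 12.0.3.1. The deposited processed intensity is, in Agilent's software, the spot intensity after background correction, and the headers read here give the protocol's name but not its settings. The deposited series table holds a scaled signal, which equals the processed intensity times 1 constant per array (0.964, 1.07, 0.945 and 0.990 for control 1, PGE2 1, control 2 and PGE2 2), so that its scale, centring and direction are those of the scanner values. Its column medians are 32.7, 39.9, 42.9 and 40.5 in that order. It was used as an alternative and for gene symbols, gene IDs, pathways and cytobands. Its 4 other columns of values per sample, which hold detection calls, were not used.

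All 4 arrays carry the same scan identifier in the file headers, so there is no slide or scan batch to test. No pair of arrays held identical values. Of 62976 spots per array, 59305 are not controls. Spots of 1 probe were averaged (300 of 56605 probes have replicate spots) and 158 probes with outlier flags were left out. The main values are log2 of the processed intensity minus each array's 75th percentile of it. A probe was kept if it was well above background on both arrays of at least 1 group (26100 probes), and each gene was represented by its kept probe with the highest mean signal over the 4 arrays, which gave 17660 tested genes or unnamed probes, 14310 with a symbol and 3350 without. Of 47700 non-control spots with a symbol, 44970 matched a gene ID of the RefSeq table of assembly GRCm38.p6, which updated 2199 symbols. The others kept the name in the file. As that assembly is not the array's build, none of its coordinates was used. The percentile scaling sets each array's 75th percentile to 0, so a change shared by most transcripts would not show, and values near background are noisy on the log2 scale. Several probes below background on all arrays lay instead near a common value per array. Both Mmp9 probes and a second Has1 probe thus differed by -0.52 between the groups.

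PGE2 was compared with control by limma (version 3.58.1 in R 4.3.3; tables were read with the data.table package, version 1.17.8) with lmFit and eBayes, 2 residual and 2.15 prior degrees of freedom, and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. Fixed lists of genes (41 lists, of which 40 had at least 5 tested genes) were tested with camera at a preset correlation of 0.01 between genes, with the correlation estimated from the data and with fry, each adjusted over the lists. With an estimated correlation, camera rests on the 2 residual degrees of freedom, so it can hardly call any list here. Of 843 tested genes on any list, 42 stand on more than 1. The gene lists, the tests, the rule for named genes and the alternative settings were fixed before the data were examined. The rule named 17 key genes whatever their result, the 10 largest rises and 10 largest falls, by fitted value, among called genes whose PGE2 arrays both lay beyond both control arrays (clone, probe, LOC, Gm-number and Rik names left out), and, for each list past its threshold, up to 4 members with the smallest p in its direction and up to 2 called members against it, or otherwise up to 2 called members. Of 28 named genes with more than 1 kept probe, the probes differed in sign in 1, Pde4d.

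The steps were tested on simulated data made from the 17660 tested genes with 200 genes changed in each of 20 simulations of the PGE2 comparison. The fit called 0.3% of 2-fold, 20.4% of 4-fold and 82.7% of 16-fold changes, with 3.8 false calls per simulation, so moderate changes mostly went uncalled in this setting. A list of 22 genes, each shifted by -1 on the log2 scale, was called in 20 of 20 simulations, and on average 0 of 38 other lists were. Genes were simulated independently of each other, while estimated correlations within the real lists reached 0.89. The simulation therefore does not show how often a list of correlated genes is called falsely. Its shares of called genes and its false calls need not hold for the data either. More genes than 200 may have changed there, and no array effect shared across genes was simulated.

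The alternatives were quantile normalization, centring on the median of tested genes, normexp background correction (offset 50) with quantile normalization, the authors' scaled values, no filter on dim probes, a filter requiring all 4 arrays, all probes, the mean of a gene's probes, eBayes with trend and robust, the replicate number as a block, leaving out each array, a minimum fold of 2, an adjusted p under 0.10, and the other gene set tests. The files hold no mean signal, so normexp used the median signal of each spot, which is a change from the plan. Scaling on the 75th percentile of probes above background on all arrays, and scaling on the E1A spike-in probes, were added after seeing the data.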

Results

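RNA from cultured mouse aortic vascular smooth muscle cells was measured on 4 single-colour Agilent arrays. The cells were grown out of explanted adult aorta of the C57BL/6J strain and carried a genotype that the labels give as EP4-Tg. EP4 is a receptor for prostaglandin E2 (PGE2) that couples to Gs and raises cyclic AMP, and the mouse gene is Ptger4. There were 2 control cultures left without treatment for 24 h and 2 cultures given PGE2, also with a time of 24 h. Each is described as a biological replicate. The dose of PGE2 is not given in the sources used here, and cells of another genotype were not analysed here, so the comparison asks which transcripts differed with PGE2 in these cells and not what the genotype contributes.

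Between 47.9% and 53.8% of the 59305 non-control spots on an array were well above background, and none of these spots was saturated. After scaling, 17660 genes or unnamed probes were tested. Across these, arrays of the same group correlated at r = 0.974 for control and r = 0.978 for PGE2, and arrays of different groups at r = 0.943 to 0.958. These correlations are across genes, which are not independent replicates. The number of arrays, 2 per group, limits the precision of every value. Log2 changes are given as PGE2 minus control with the standard error of the limma fit (n = 2 per group). A gene whose probes were not well above background on any array of a group has only a bound there. Its change is given as "at least N-fold", from the mean of the brighter group against a floor set on each array by the dimmest signal well above background or by the probe itself, whichever was higher.

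With PGE2, 70 genes were higher and 48 were lower at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment). The phosphodiesterase genes Pde4b and Pde4d, the chemokine gene Cxcl1, the complement gene C3 and the protease inhibitor gene Timp1 rose, and the genes of elastin, integrin alpha 8 and endothelin 1 fell. In each of the 118 called genes both PGE2 arrays lay beyond both control arrays, which a call with 2 arrays per group nearly requires. This was so in 52.2% of all tested genes against 33.3% by chance. That chance share leaves out the filter, which keeps probes above background in only 1 group, and array effects shared across genes. Of the called genes, 32 of those that rose were not well above background on either control array on any probe, and 27 of those that fell were not on either PGE2 array. In these the adjusted p rests partly on signals below background, whose spread need not be that between cultures. The smallest fitted change among called genes was 3.30-fold, though a gene with only a bound may have changed by less (Ptgfr, at least 2.25-fold). The calls sat close to the threshold, with adjusted p values from 0.0438 to 0.0492, and 3151 genes had an unadjusted p under 0.05 where 883 would by chance. Limma called 0 genes on the authors' deposited scaled values, where 4204 genes had an unadjusted p under 0.05, and 0 genes without control replicate 1 or without control replicate 2, where 2712 and 2963 did. It also called 0 genes without the filter on dim probes (2685 at an unadjusted p under 0.05), and 98 higher and 76 lower genes without PGE2 replicate 2, of which 42 and 29 were among the 70 and 48.

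**Figure D1:**
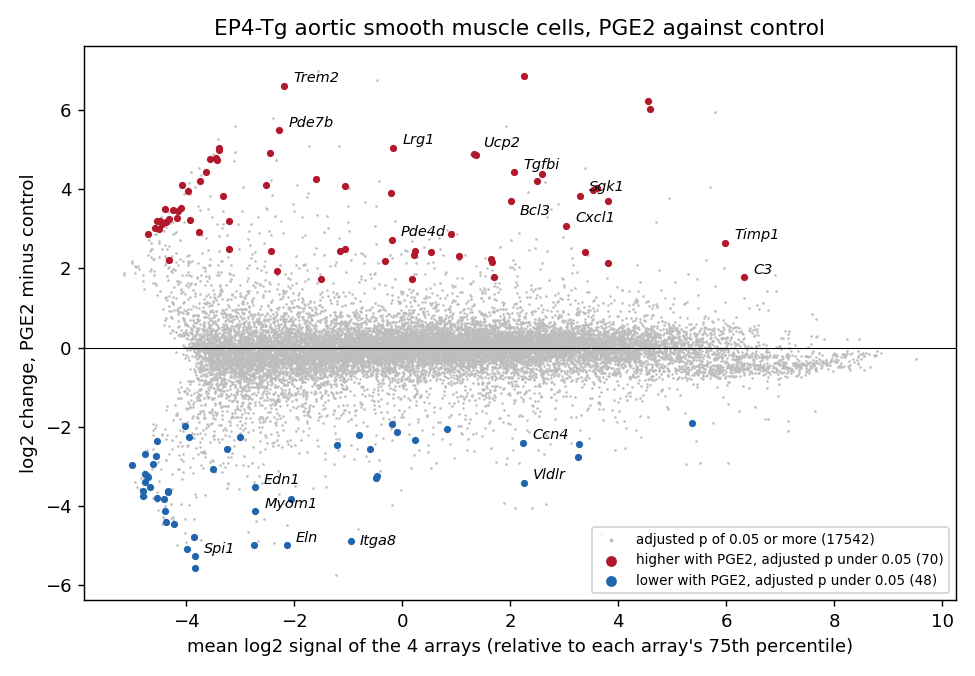
Log2 change (PGE2 minus control, vertical axis) against the mean log2 signal of the 4 arrays (horizontal axis) for each of the 17660 tested genes or probes. The 70 genes called higher are red, the 48 called lower are blue and the rest are grey, and most of the called genes with a low mean signal lie below background in 1 of the groups.

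The 10 rises and 10 falls in this paragraph and the next were taken by their fitted values, an order that signals below background can inflate and the bounds do not support. Of the rises, Trem2, an immunoglobulin-family receptor best known from myeloid cells, was at least 30.5-fold higher with PGE2 (adjusted p = 0.0438, limma). The phosphodiesterase Pde7b was at least 19.5-fold higher, and Tnfrsf9, a costimulatory receptor of the TNF receptor family also called 4-1BB, at least 14.1-fold (both adjusted p = 0.0465). A second, dimmer Tnfrsf9 probe, stood at 1.88 against control signals that were also below background. Lrg1, a secreted leucine-rich glycoprotein, was measured in both groups and rose by 5.04 ± 0.45 on the log2 scale (adjusted p = 0.0465). Ucp2, a mitochondrial carrier, rose by 4.89 ± 0.39. The probe for its neighbour Ucp3 in the same cytoband, 7qE3, gave 4.86 ± 0.40, a value that is uncertain because the probe may read transcripts of Ucp2. The potassium channel subunit gene Kcng4 was at least 7.69-fold higher, the calcitonin and CGRP gene Calca at least 7.59-fold, the trypsin gene Try5 at least 6.82-fold and Traf3ip3 at least 6.70-fold, all from control signals not well above background. The second probes of Kcng4 and Calca were not well above background on any array, and that of Pde7b was on 1 PGE2 array only. Trypsin genes form a family of close copies, so the Try5 value is uncertain.

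Of the 10 falls, Eln, which encodes elastin, was at least 25.1-fold lower with PGE2 (adjusted p = 0.0438, limma). Both of its probes were well above background on the 2 control arrays and on no PGE2 array. Itga8, the alpha 8 integrin subunit of contractile smooth muscle, was measured on all 4 arrays and fell by 4.88 ± 0.32 on the log2 scale (adjusted p = 0.0438), with a second, dimmer probe above background on the control arrays only. Myom1, a sarcomere M-band protein gene, was at least 12.9-fold lower, and Edn1, the precursor of the vasoconstrictor endothelin 1, at least 10.4-fold lower (adjusted p = 0.0438 and 0.0449). The transcription factor genes Spi1 and Bcl11b, both best known from blood cells, were at least 8.87-fold and at least 7.48-fold lower. Smaller bounds held for B3gnt8, a glycosyltransferase gene, at 7.39-fold and for the ectodysplasin receptor gene Edar at 3.54-fold. The second probes of Myom1, Bcl11b and Edar were not well above background on any array. The metalloprotease gene Adam12 and the T-cell gene Themis were called lower on 1 probe each (both adjusted p = 0.0465), without a bound, because another probe of each was above background on 1 PGE2 array. Those probes did not pass the filter.

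Cyclic AMP is the second messenger of EP4, and the list of cAMP and CREB target genes was higher as a set with PGE2 (camera adjusted p = 0.00018, median log2 change 0.73 over 26 tested genes). The call was lost, with adjusted p = 0.77 with an estimated correlation, and the median was 1.18 without control replicate 1. Of the 26 genes, 2 rose and 0 fell over all genes tested, and 11 rose and 3 fell when adjusted over the list alone. The phosphodiesterase genes Pde4b and Pde4d, whose enzymes break down cyclic AMP, rose by 2.32 ± 0.19 and 2.71 ± 0.24 on the log2 scale (both adjusted p = 0.0465, limma). The 5 measured probes of Pde4d did not move alike, with changes from -0.94, on a probe above background on 1 of 2 control arrays, to 3.04. The cyclic nucleotide phosphodiesterase gene Pde10a stood at 2.85 ± 0.26 (adjusted p = 0.0508), the cyclic AMP response gene Crem at 2.49 ± 0.25 (adjusted p = 0.0558) and the clock gene Per1 at 1.52 ± 0.16 (adjusted p = 0.0616), just outside the threshold. The nuclear receptor gene Nr4a1, an immediate early gene, stood at 0.86 ± 0.50 (adjusted p = 0.447), or 1.52 without control replicate 1 and 0.20 without control replicate 2. In the wider list of G-protein signalling genes, cyclases and phosphodiesterases, 3 of 35 rose, which were Pde4b, Pde4d and Pde7b, against 6 higher and 2 lower adjusted over the list alone, and the list did not pass as a set (adjusted p = 0.34, median -0.06).

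Of the prostanoid genes, Ptgfr, which encodes the receptor for prostaglandin F2 alpha, was at least 2.25-fold higher with PGE2 (adjusted p = 0.0465, limma). A second Ptgfr probe was not well above background on any array. It was the only called gene among 13 tested, against 2 higher and 2 lower adjusted over the list alone, and the list did not pass as a set (adjusted p = 0.63, median 0.09). Ptger4 itself was dim. It was above background on 1 of 2 control arrays and on both PGE2 arrays, at 0.59 ± 0.70 on the log2 scale (adjusted p = 0.696), a change that turned to -0.38 without control replicate 1 and was 1.56 without control replicate 2. The labels do not say which part of the receptor the EP4-Tg genotype carries, or of which species, so these probes do not measure the genotype. Ptger2, the gene of the other Gs-coupled PGE2 receptor, was not well above background on any array and was not tested. Ptgs2, the inducible cyclooxygenase gene, stood at 1.26 ± 0.94 (adjusted p = 0.539), or 2.30 without control replicate 1 and 0.23 without control replicate 2, and Ptges, a PGE2 synthase gene, at -0.03 ± 0.15 (adjusted p = 0.947), with a sign that depended on the scaling.

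Contractile smooth muscle genes were lower as a set with PGE2 (camera adjusted p = 5.9e-06), a call that was lost, with adjusted p = 0.77 with an estimated correlation. The median log2 change of the 22 tested genes was -1.42, or -0.82 without PGE2 replicate 1, and 21 of them had a value below 0. Itga8 was the only gene of the list that fell over all genes tested, while 0 rose and 6 fell when adjusted over the list alone. The smooth muscle actin gene Acta2 stood at -2.10 ± 0.46 (adjusted p = 0.152, limma) and the actin-binding transgelin gene Tagln at -1.79 ± 0.35 (adjusted p = 0.134). The Z-disc gene Ldb3, the vinculin gene Vcl and Ppp1r14a, which encodes an inhibitor of myosin phosphatase, stood at -1.89 ± 0.24, -1.50 ± 0.23 and -2.61 ± 0.48 (adjusted p = 0.0759, 0.0962 and 0.123), with a second Ldb3 probe at -0.69 and Ppp1r14a above background on 1 of 2 PGE2 arrays. Myh11, the smooth muscle myosin heavy chain gene, did not reach the filter on any of its 4 probes and was not tested. The list of genes driven by YAP and by the actin-sensing cofactors of SRF, which shares Vcl, had 0 called genes among 26 (median -0.36, adjusted p = 0.062). It passed as lower in 7 of 16 alternatives of the unpaired fit, among them those without control replicate 2 (set adjusted p = 0.0438) and without PGE2 replicate 2 (0.00824).

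The elastic fibre genes had Eln as the only fall over all genes tested, among 21 tested. The list did not pass as a set (camera adjusted p = 0.13, median -0.28), with 1 higher and 2 lower adjusted over the list alone. It did pass, as lower, without control replicate 1 (median -0.48) and without PGE2 replicate 2 (median -0.40). Lox, whose enzyme cross-links elastin and collagen, stood at -0.72 ± 0.18 (adjusted p = 0.180, limma). None of the 26 collagen and collagen-processing genes was called, against 0 higher and 4 lower adjusted over the list alone. The collagen list did not pass (adjusted p = 0.078, median -0.38) but did, as lower, without control replicate 2 (median -0.65) and without PGE2 replicate 2 (median -0.42). Among 28 matrix glycoprotein, proteoglycan and hyaluronan synthase genes, Has1, a hyaluronan synthase gene, was at least 5.29-fold higher (adjusted p = 0.0465). A second Has1 probe was not well above background on any array. Has2, another hyaluronan synthase gene, stood at 1.75 ± 1.19 (adjusted p = 0.504), or 3.28 without PGE2 replicate 1 and 0.21 without PGE2 replicate 2, and was above background on 1 of 2 control arrays. That list had 4 higher and 8 lower genes adjusted over the list alone and did not pass as a set (adjusted p = 0.26, median -0.58), but did, as lower, without PGE2 replicate 2 (0.0204).

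Of the 25 tested matrix proteases and inhibitors, Timp1, an inhibitor of matrix metalloproteases, rose by 2.63 ± 0.15 on the log2 scale from an already bright signal (adjusted p = 0.0438, limma). The gelatinase gene Mmp2 stood at -0.54 ± 0.23 (adjusted p = 0.324). Mmp9, the other gelatinase gene, was not well above background on any array and was not tested. The list had 4 higher and 1 lower gene adjusted over the list alone and did not pass as a set (adjusted p = 0.84, median -0.22).

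**Figure D2:**
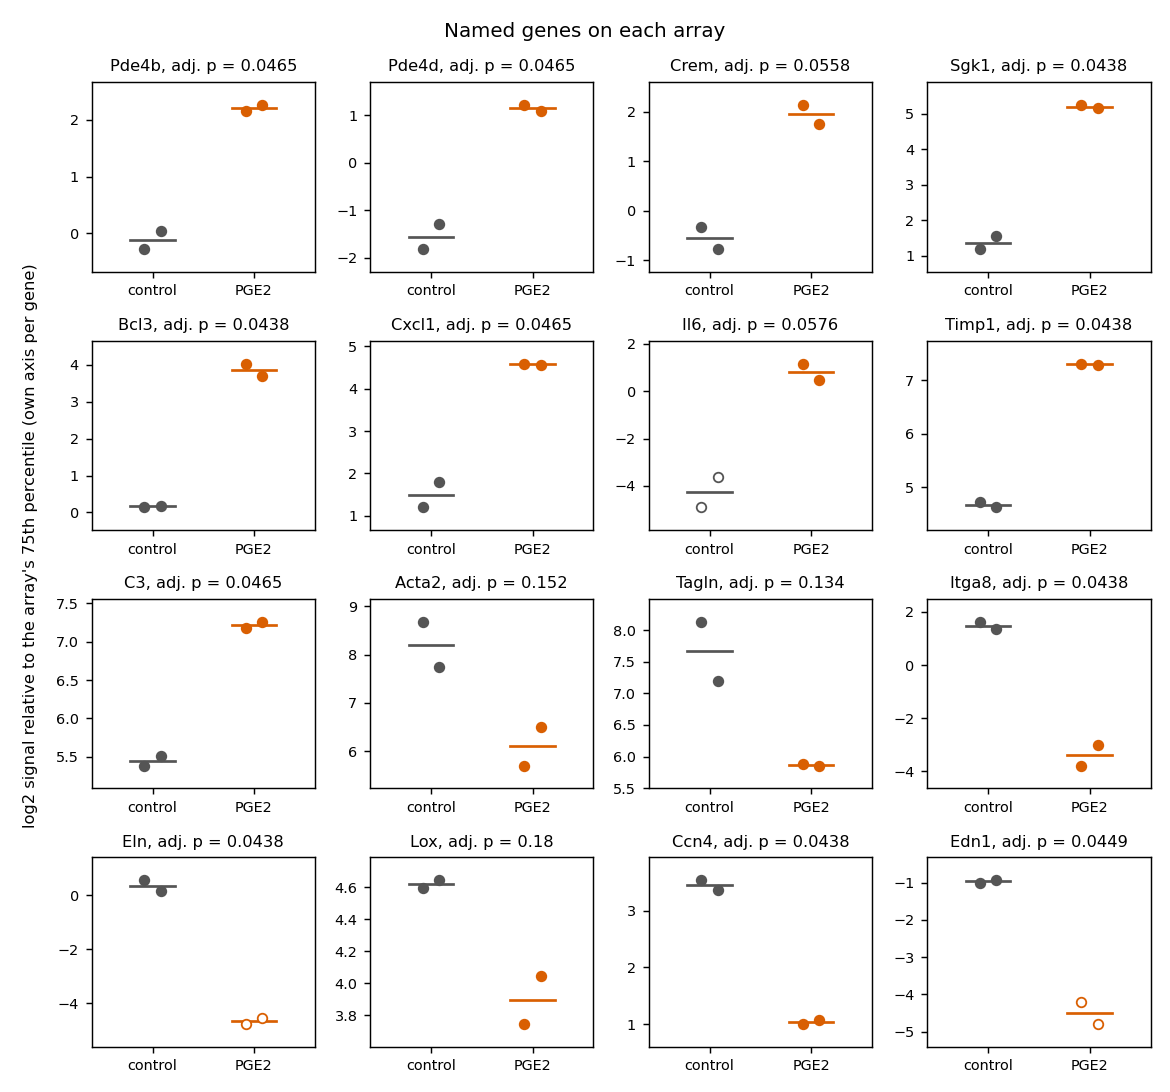
Log2 signal relative to the array's 75th percentile (vertical axis, a separate range for each gene) of 16 named genes on the 2 control arrays (grey) and the 2 PGE2 arrays (orange), with a line at each group's mean. Open circles mark groups in which the tested probe was not well above background on either array, and the adjusted p of the limma fit stands above each panel, 0.0438 for Eln and 0.152 for Acta2.

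Among 22 cytokine, chemokine and adhesion genes, Cxcl1, a neutrophil chemoattractant gene, rose by 3.07 ± 0.25 on the log2 scale (adjusted p = 0.0465, limma). Il6 was not well above background on either control array and was well above it on both PGE2 arrays, a difference of at least 4.64 on the log2 scale with an adjusted p = 0.0576, just outside the threshold. Ccl2, a monocyte chemoattractant gene, stood at 1.12 ± 0.82 (adjusted p = 0.533), or 2.25 without control replicate 1 and -0.01 without control replicate 2. The list had 4 higher and 3 lower genes adjusted over the list alone and did not pass as a set (adjusted p = 0.25, median 0.79, or 0.59 with dim genes at their bound), but did, as higher, without PGE2 replicate 1 (median 1.63, 0.00147). Its median turned to -0.52 without the filter on dim probes and to -0.15 with the filter for all 4 arrays. Bcl3, a nuclear cofactor of NF-kB, rose by 3.70 ± 0.19 (adjusted p = 0.0438) as the only called gene of 24 in the NF-kB list, against 2 higher and 1 lower adjusted over the list alone (set adjusted p = 0.84, median 0.01). C3, the central complement component, rose by 1.77 ± 0.16 (adjusted p = 0.0465) as the only called gene of 12 in the complement list, against 2 higher and 2 lower adjusted over the list alone (set adjusted p = 0.75, median 0.26). None of the 28 interferon-stimulated genes or 14 genes of MHC class I presentation was called. Adjusted over the list alone, 1 interferon-stimulated gene was higher and 1 lower, and 0 of the MHC genes passed (medians -0.36 and -0.20, set adjusted p = 0.24 and 0.28). The interferon list passed as lower without control replicate 1 (median -0.64) and without PGE2 replicate 2 (median -0.33).

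Genes of G2/M and mitosis were lower as a set with PGE2 (camera adjusted p = 1.1e-06), a call that was lost, with adjusted p = 0.92 with an estimated correlation. Their median log2 change was -0.76, or -0.37 with normexp and quantile normalization and -0.50 on the authors' scale, and 24 of the 25 tested genes had a value below 0. No gene of the list was called over all genes tested, and 0 rose and 7 fell adjusted over the list alone. Anln and Ccnb2, genes of cytokinesis and of a mitotic cyclin, stood at -3.04 ± 0.41 and -1.55 ± 0.22 (adjusted p = 0.0820 and 0.0868, limma), and the proliferation marker gene Mki67 at -2.12 ± 0.43 (adjusted p = 0.137). The 30 genes of DNA replication and G1/S did not pass as a set (adjusted p = 0.27, median -0.11), with 0 called by either adjustment. They did pass, as lower, without control replicate 1 (median -0.32). The p53 target list was also lower as a set (adjusted p = 1.2e-05, median -0.61 over 24 genes, or -0.35 on the authors' scale), with adjusted p = 0.77 with an estimated correlation. None of its genes was called over all genes tested, while 0 rose and 7 fell adjusted over the list alone. The apoptosis gene Bbc3 stood at -1.51 ± 0.20, the membrane protein gene Perp at -1.44 ± 0.23 and the cell cycle inhibitor gene Cdkn1a at -1.16 ± 0.21 (adjusted p = 0.0772, 0.103 and 0.120).

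Ribosomal protein genes were lower as a set by a small amount (camera adjusted p = 2.6e-09, median -0.46, all 37 tested genes below 0). The adjusted p = 0.92 with an estimated correlation of 0.89. No gene of the list was called by either adjustment, and the lowest, Rps7, stood at -0.71 ± 0.19 (adjusted p = 0.190, limma). The call was also lost under quantile normalization (median -0.04, set adjusted p = 0.198), with normexp and quantile normalization (median -0.05, set adjusted p = 0.201) and in fry (adjusted p = 0.26). It was kept on the authors' scale (median -0.20), with median centring, with the percentile over detected probes and on the spike-in scale. These scalings move all genes of an array by the same amount, so they keep the difference between the ribosomal genes and the other genes. They can still change set calls, with 12 lower lists on the authors' scale against 5 in the main fit. As the difference itself is kept by construction, the kept ribosomal call is no support for it. The 36 oxidative phosphorylation genes lay at the threshold (adjusted p = 0.050, median 0.14), with 0 called by either adjustment. The list passed as higher in 10 of 16 alternatives of the unpaired fit, among them quantile normalization (median 0.20, set adjusted p = 0.00289) and the fits without control replicate 1 (0.32, 0.000303) and without PGE2 replicate 2 (0.23, 0.0373), and not with an estimated correlation (adjusted p = 0.92).

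Metabolic lists moved in both directions. Fatty acid synthesis and lipid storage genes were higher as a set (camera adjusted p = 6.8e-05, median 0.43 over 25 genes, or 0.69 on the authors' scale), with adjusted p = 0.77 with an estimated correlation and 0.022 in the rotation test fry. No gene of the list was called over all genes tested, while 8 rose and 1 fell adjusted over the list alone. The acyl-CoA synthetase gene Acsl4 stood at 2.33 ± 0.22, the triglyceride synthesis gene Dgat2 at 1.92 ± 0.27, the lipid droplet gene Plin2 at 1.24 ± 0.15 and the lipogenic regulator gene Srebf1 at 0.99 ± 0.15 (adjusted p = 0.0539, 0.0868, 0.0707 and 0.0950, limma). Genes of cholesterol synthesis and uptake were lower as a set (adjusted p = 0.026, median -0.56 over 23 genes), with adjusted p = 0.92 with an estimated correlation and 0 called by either adjustment. Their leading gene was Sqle, the squalene epoxidase gene, at -1.32 ± 0.25 (adjusted p = 0.125). The cholesterol call was also lost without control replicate 1 (median -0.10, set adjusted p = 0.587), without the filter on dim probes (set adjusted p = 0.240) and in fry (adjusted p = 0.53), and the median was -0.96 without control replicate 2 and -0.30 on the authors' scale. The 31 glycolysis and hypoxia genes, at a median of -0.08, had 0 called by either adjustment (set adjusted p = 0.78, or 0.0279, as higher, without PGE2 replicate 1).

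Clock genes and glucocorticoid target genes were higher as sets. The circadian list had a median of 0.66 over 18 genes, or 0.39 with dim genes at their bound (camera adjusted p = 0.0077), with adjusted p = 0.92 with an estimated correlation, and the median was 0.43 without control replicate 1, 0.25 with normexp and quantile normalization and 0.34 without the filter on dim probes. No clock gene was called over all genes tested, while 6 rose and 0 fell adjusted over the list alone. The circadian repressor genes Nfil3 and Bhlhe40 stood at 2.21 ± 0.30 and 1.38 ± 0.33, and the output regulator Dbp at 1.09 ± 0.25 (adjusted p = 0.0812, 0.167 and 0.159, limma). The glucocorticoid list had a median of 0.37 over 19 genes (adjusted p = 0.0049), with adjusted p = 0.77 with an estimated correlation, and on the authors' scaled values its set adjusted p was 0.114 and its median 0.63. The median was 0.92 with the mean of a gene's probes, 0.58 with normexp and quantile normalization, 0.86 without control replicate 1, 0.66 without control replicate 2 and 0.57 without PGE2 replicate 1. In that list Sgk1, a kinase gene that also responds to other stimuli, rose by 3.82 ± 0.19 and the sulfotransferase gene Sult1a1 fell by 3.25 ± 0.20 (both adjusted p = 0.0438), against 7 higher and 1 lower adjusted over the list alone. Cebpd and Lcn2, genes also known from the acute-phase response, stood at 2.00 ± 0.27 and 3.05 ± 0.49 (adjusted p = 0.0826 and 0.103). Per1 stands on the cAMP, circadian and glucocorticoid lists, so these lists are not independent.

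**Figure D3:**
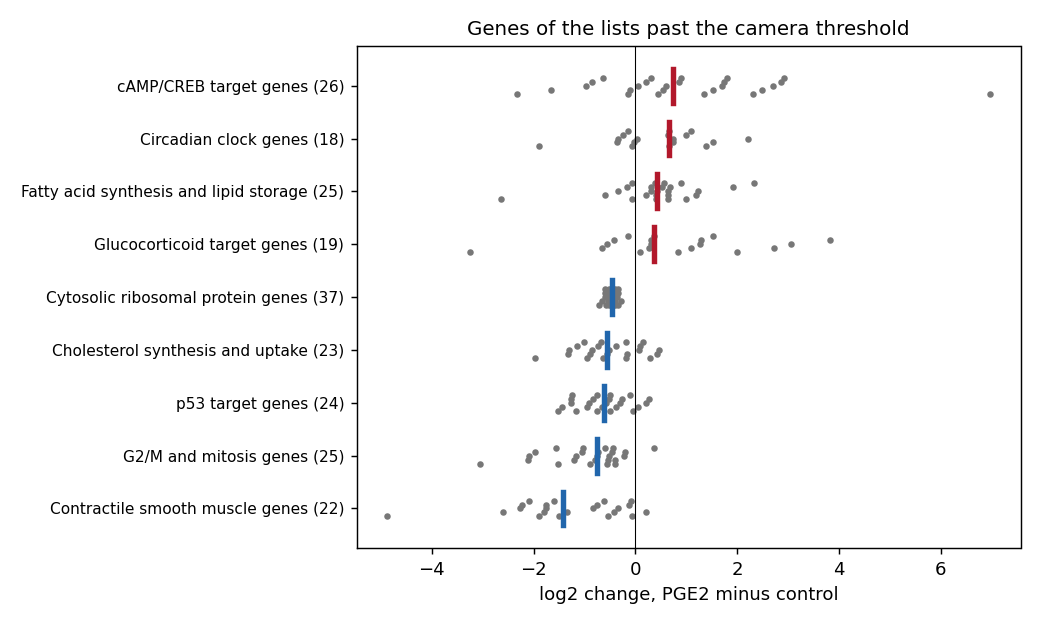
Log2 change (PGE2 minus control, horizontal axis) of each tested gene of the 9 lists past the camera threshold, with the number of genes tested in parentheses. Each grey point is a gene and the bar is the list's median, red for the 4 lists higher with PGE2 and blue for the 5 lower, from 0.73 for the cAMP and CREB targets to -1.42 for the contractile genes.

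In all, 4 of 40 tested lists were higher and 5 lower with the preset correlation. Of the 9 calls, 0 held with an estimated correlation and 1, that of the fatty acid list, in fry. Camera with an estimated correlation had 2 residual degrees of freedom and a smallest adjusted p of 0.77, so it could hardly keep any call. For the cAMP, fatty acid and glucocorticoid lists the estimated correlation was -0.016, -0.041 and -0.033, below the preset 0.01. In these lists the loss does not show that correlation between genes made the call. For the contractile, G2/M and p53 lists the estimate was 0.12, 0.28 and 0.09. For the circadian, cholesterol and ribosomal lists it was 0.25, 0.83 and 0.89. These estimates lie above the preset, so the adjusted p values of these lists at the preset may be too small. The count of lower lists was 12 without PGE2 replicate 2, 8 without control replicate 2 and 12 on the authors' scaled values, and that of higher lists was 7 without PGE2 replicate 1. Single genes were called in several lists that did not pass as a set. Tgfbi, a matrix protein gene named for its induction by TGF-beta, rose by 4.42 ± 0.31 (adjusted p = 0.0451, limma) in a list of 28 TGF-beta targets with 4 higher and 4 lower adjusted over the list alone (set adjusted p = 0.76, median -0.05). Vldlr, a lipoprotein receptor gene, fell by 3.41 ± 0.23 and Stc2, a secreted glycoprotein gene, fell by 2.26 ± 0.18 (adjusted p = 0.0438 and 0.0465). They were the only called genes among 32 of the unfolded protein and integrated stress response, where 0 rose and 2 fell adjusted over the list alone (set adjusted p = 0.63, median -0.12). The stress response list passed as lower without control replicate 2, at a median of -0.32. Stc2, above background on 1 of 2 PGE2 arrays, was also the only called gene of 14 IGF-binding protein and stanniocalcin genes, and the only one adjusted over the list alone (set adjusted p = 0.41, median 0.28). That list passed as higher without PGE2 replicate 1, at a median of 0.84. Ccn4, a matricellular Wnt target, fell by 2.40 ± 0.16 (adjusted p = 0.0438) in the list of 28 growth and angiogenic factors, against 2 higher and 6 lower adjusted over the list alone (set adjusted p = 0.13, median -0.34). The growth factor list passed as lower without PGE2 replicate 2, at a median of -0.62. Rspo1, an amplifier of Wnt signals, was at least 4.96-fold lower (adjusted p = 0.0438) among 27 Wnt pathway genes, against 4 higher and 5 lower adjusted over the list alone (set adjusted p = 0.99, median 0.04).

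The remaining lists of pathways had no called gene. Adjusted over the list alone, 0 passed among 28 NRF2 and metallothionein genes, 23 osteochondrogenic genes, 30 ion channel and calcium-handling genes and 16 housekeeping genes, and 1 was higher and 1 lower among 14 Notch genes. Their medians were 0.10, -0.33, -0.19, 0.06 and -0.08 and their set adjusted p values 0.13, 0.84, 0.84, 0.90 and 0.97. The NRF2 list passed as higher without control replicate 1 (median 0.39) and without PGE2 replicate 2 (median 0.23). In 10 lists, none of them past the threshold, the median and the set test had opposite signs. These were the matrix protease, glycolysis, TGF-beta, Wnt, Notch, G-protein signalling, fibroblast, pericyte, neural and housekeeping lists, and the mean also differed in sign from the median in all of them except the matrix protease and TGF-beta lists.

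None of the marker lists of other cell types passed as a set. Of 16 tested fibroblast markers, Ly6a and Ly6c1 rose by 4.20 ± 0.28 and 3.99 ± 0.22 on the log2 scale (both adjusted p = 0.0438, limma), against 4 higher and 2 lower adjusted over the list alone (set adjusted p = 0.76, median -0.25). Both belong to a family of close copies in cytoband 15qD3 and are also known from blood and endothelial cells. Tubb3, a neuronal tubulin gene, rose by 2.23 ± 0.15 (adjusted p = 0.0438) among 7 tested Schwann and neural markers, against 1 higher and 1 lower adjusted over the list alone (set adjusted p = 0.84, median -0.25). No marker was called among 9 endothelial, 6 macrophage and leukocyte, 6 adipocyte, 8 pericyte and 4 epithelial and mesothelial genes. Adjusted over the list alone, 0 endothelial and 0 adipocyte markers passed, 1 macrophage and leukocyte marker was higher, 2 pericyte markers were higher and 1 lower, and 1 epithelial or mesothelial marker was higher and 2 lower. All 9 endothelial markers had values below 0 (median -0.51, set adjusted p = 0.12, or 0.0267, as lower, without PGE2 replicate 2). The medians of the macrophage, adipocyte and pericyte lists were 0.25, -0.10 and -0.07 with set adjusted p values of 0.53, 0.75 and 0.90, and the epithelial and mesothelial list, at a median of -0.76, had too few tested genes for a set test.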

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

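Scaling on probes above background on all arrays, scaling on the E1A spike-ins and normexp on the median signal were chosen after seeing the data. The counts of 70 higher and 48 lower genes stayed within 1.5 times under quantile normalization, median centring, normexp, all probes, the mean of a gene's probes, trend and robust, and a minimum fold of 2, but the calls shared were 47 and 29 with quantile normalization, 45 and 21 with normexp, and 50 and 27 with trend and robust. Limma called 0 higher and 0 lower genes on the authors' scaled values (smallest adjusted p = 0.0564), without a filter (0.214), with the percentile over detected probes (0.067) and on the spike-in scale (0.0689), where 4204, 2685, 3520 and 2826 genes had an unadjusted p under 0.05. The filter for all 4 arrays gave 39 and 15, since it leaves out genes below background in 1 group, and an adjusted p under 0.10 gave 240 and 259. Leaving out 1 array gave 0 to 98 higher and 0 to 76 lower genes. Here the lone array of a group is assumed to vary like the other group. Either control left out gave 0 calls, and PGE2 replicate 2 left out gave 98 and 76. The authors' scale moved the median change of all tested genes from -0.03 to 0.23, so its changes are relative to that shift. The replicate block gave 88 and 84 calls, with 49 and 35 of them shared with the unblocked fit, ended the call of the cholesterol list (adjusted p = 0.0625) and called the oxidative phosphorylation and endothelial lists (both 0.0277). Deviations of same-numbered arrays from their group means correlated at r = 0.42 across genes, but nothing in the labels pairs them. Of the gene lists, 4 higher and 5 lower became 0 and 0 with an estimated correlation and 1 and 0 with fry. The lower lists rose to 12 on the authors' scale, 8 with the filter for all 4 arrays and 8 on the spike-in scale, and the higher lists to 9 without a filter. Leaving out 1 array gave 4 to 7 higher and 5 to 12 lower lists. Unless stated, the cause was not tested. No called gene or list reversed. As the groups of the 118 called genes do not overlap, only another scaling or choice of probes could do that to a gene. Of the uncalled named genes, Ptger4, Ptges and Ccl2 changed sign in 5 of 1176 values of named genes. A slide block was not run, as the arrays share 1 scan. Signal over background limits 32 of the higher and 27 of the lower genes to bounds.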

Other observations

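The tests of explanations in this part were chosen after the results were seen, and so were the genes and probes named here outside the fixed rule.

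The largest called rise measured in both groups came from an unnamed probe, A_52_P49797, which rose by 6.86 on the log2 scale with PGE2 (adjusted p = 0.0465, limma, n = 2 per group). The series table places it at cytoband 17qA2 and gives it the same transcript assembly as 2 other probes, A_55_P2088720 at 7qA2 and the probe of 3930401B19Rik at 13qB1. These rose by 6.22 and 6.02, and all 3 were well above background on all 4 arrays. By fitted value, 7 of the 26100 kept probes had a larger rise than the smallest of these, the other 2 among them. The probe of Trem2 is also among the 7, with control signals not well above background, so this order is not exact. That a single assembly is listed at 3 cytobands leaves open which locus was transcribed, and the sequence was not analysed here.

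Steap4, a metalloreductase gene, was at least 4.64-fold higher with PGE2 (adjusted p = 0.0438, limma). Cav1, the caveolin gene, fell by 3.28 (adjusted p = 0.0465). Of 272 KEGG pathways named in the series table, 0 were higher and 2 lower by camera with the preset correlation. The ECM-receptor interaction pathway had a median of -0.57 over 55 genes (adjusted p = 0.0064) and the Ribosome pathway -0.41 over 130 (adjusted p = 0.00014), and both had an adjusted p = 0.99 with an estimated correlation. Apart from Ribosome, the pathways taken as closest in name to called lists did not pass. Medians were 0.03 for Cell cycle and -0.15 for Vascular smooth muscle contraction (camera adjusted p = 0.88 and 0.59). The cAMP signaling pathway stood at -0.06 and p53 signaling at -0.25 (0.80 and 0.15). Steroid biosynthesis stood at -0.18, Fatty acid metabolism at 0.08 and Circadian rhythm at 0.22 (0.68, 0.47 and 0.22). These pathways and the lists are not the same sets of genes.

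Of the 2 other ways to split the 4 arrays evenly, replicate 1 against replicate 2 gave 0 calls, with 879 genes at an unadjusted p under 0.05, and the crossed split gave 0 calls, with 95. The real split gave 118 calls. With 3 splits in all, the share of splits as extreme as the real one cannot be under 0.05.

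All 37 ribosomal protein genes were lower with PGE2, by a median of 0.46 on the log2 scale, a small shift in very bright transcripts whose set call was lost, with adjusted p = 0.92 with an estimated correlation. An intensity-dependent bias between arrays may produce it, and the 3 brightest E1A spike-in probes changed by -0.12 ± 0.18 (SE between arrays), too wide to tell a bias of that size from none. A shift shared by all bright transcripts is the other candidate explanation, and other genes matched on mean signal had a median of -0.31 over 10000 random lists, and the ribosomal median lay at percentile 0.15 of them, but such lists treat genes as independent while the estimated correlation within the list was 0.89. Judged on these lists alone, as first set, the shared shift fell short of the whole difference, but quantile normalization left a median of -0.04 with an adjusted p = 0.198. These explanations and an effect of PGE2 on ribosomal protein transcripts cannot be told apart.

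Contractile genes were lower as a set with PGE2, a call that was lost, with adjusted p = 0.77 with an estimated correlation. A higher share of fibroblasts in these cultures could lower them by dilution. It would raise abundant fibroblast transcripts, yet the 5 fibroblast markers with the highest control signal had a median change of -0.68, with all 5 below 0. These are S100a4, Dcn, Gsn, Lum and Smoc2. The standard error over them, 0.55, is that of their mean and does not measure the precision of the median. Other markers of the list went the other way, with Ly6a at 4.20, Ly6c1 at 3.99, Gfpt2 at 3.34 (above background on 1 of 2 control arrays) and Pi16 at 2.78, and 4 rose and 2 fell adjusted over the list alone. This spread over the markers, and the possibility that fibroblasts themselves respond to PGE2, keep this open, so a change in cell make-up and a change within smooth muscle cells cannot be told apart.

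Trem2, best known from macrophages, was well above background on both PGE2 arrays and on neither control array, and macrophage RNA in the PGE2 cultures is a possible explanation. It would bring the abundant transcripts of these cells, but 0 of the 5 transcripts Lyz2, Tyrobp, C1qa, C1qb and C1qc were well above background on both PGE2 arrays. C1qa was above it on 1 of them, so the rule as first set, none of the 5 on any PGE2 array, was not met, and a looser rule tried later, none on both, would have excluded this source. Of the 22 measured genes of the macrophage and leukocyte list, 6 were well above background on both PGE2 arrays, all 6 on both control arrays too. They were Cd68 at 2.09 (higher adjusted over the list alone), Csf1r at 0.98, Cd14 at 0.62, Itgam at -0.61, Ptprc at -0.36 and Cd3e at -0.12. Like C1qa, Cx3cr1, Cd53, Fcer1g and Ms4a1 of this list were above background on a PGE2 array but not on both. Their dim signals were higher with PGE2 for Cx3cr1 and Cd53 and lower for Fcer1g and Ms4a1. Spi1, whose product PU.1 is a myeloid transcription factor, was at least 8.87-fold lower with PGE2. None of the 5 transcripts was well above background on both control arrays either, so the control signal of Spi1 need not come from macrophages. Its fall from the control signal therefore does not bear on this source. Spi1 was, though, not well above background on either PGE2 array, and so is also a myeloid transcript missing there. The missing transcripts go against macrophage RNA, but Cd68 goes with it and the rule does not exclude it. Thus macrophage RNA, transcription of Trem2 in the smooth muscle cells and cross-hybridisation of its single probe cannot be told apart.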
